A study of Mus musculus with 2 samples.

How the data were processed

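The series holds 2 total RNA-seq libraries of embryonic mouse midbrain, 1 per biological replicate, each from a pool of embryos. Per the labels, RNA was extracted with a mirVana kit, 10 ng of RNA longer than 200 nt entered each library, ERCC spike-ins were added, and a Smart-seq protocol is cited. Such a protocol amplifies cDNA, so reads are not independent molecules and all intervals and limits here cover counting error only. The accompanying notes name assembly mm10 and genome annotation M4, and the aligner, the quantifier and their versions are not given in the sources used here. Whether counting used strand is not given either, so antisense and overlapping genes are uncertain.

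Per the file headers, the authors deposited for each gene and transcript an expected count, which is an estimated number of reads and need not be whole. The authors also deposited TPM, in maximum likelihood and posterior mean form, and FPKM. The TPM and FPKM are scaled over all rows of a file, spike-ins included, so the spike-ins' 15.2% and 14.8% of TPM lower the level of every gene alike. The deposited interval bounds of TPM were treated as a signal without a fixed total, and their level is not given in the sources used here. Over the 13895 genes at 1 TPM in both libraries the posterior mean lay outside its interval for 0, and the maximum likelihood TPM, which is the TPM printed, for 654 in replicate 1 and 481 in replicate 2, so calls on intervals go with the posterior mean. In the deposited transcript tables a percent gives each transcript's share of its gene. Beside 43346 genes the tables held 96 spike-in rows, 1 phiX row and 26248 rows with bare numeric identifiers. Those rows were left out of gene totals and tests, and the numeric rows held 4.44 and 13.25 counts in all.

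Gene symbols came from the reference annotation (GENCODE M21, same assembly, later annotation) by identifier without version, and 42462 genes matched. Coordinates are from that annotation on mm10, 1-based. Gene lists, pairs and transcripts were fixed before the data were examined, as was the rule for named genes. That rule allows any member of a list, pair or transcript set and names the 3 highest members of each list described, the 10 highest nuclear genes, and the 10 largest log2 ratios in each direction among genes past the test with a mean count of at least 50. Spike-ins were left out, genes without a symbol are not named, and some genes that the rule takes are not reported here. There were 43 lists, and 4 listed symbols had no match (Hbb-b1, Hbb-b2, Rmst and Sox2ot).

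A gene was called detected at 1 TPM in both libraries. Lists were compared by medians of log2(TPM + 1) within each library, with 100000 two-sided permutations of genes between lists and Benjamini-Hochberg adjustment over the 4 contrasts in both libraries. A single permutation p under an alternative is the larger of the 2 libraries' values. An exact sign-flip test over 2 libraries cannot give p below 0.5, so no p over libraries is given. Pairs were compared on TPM + 0.1 and called different where the deposited intervals did not overlap, the same way, in both libraries. Replicate spread was measured with edgeR 4.0.16 (common dispersion, intercept only, TMM factors, genes at 1 CPM or more in both libraries) in R 4.3.3, on expected counts rounded to whole numbers.

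Replicate 2 was compared with replicate 1 by a two-sided exact binomial test per gene on rounded counts against TMM-scaled library sizes. Genes with a summed count of at least 20 were tested, and a call needed an adjusted p under 0.05 and an absolute log2 ratio of at least 1. List medians of log2 ratios (prior count 1) were set beside 10000 random lists matched in 20 expression bins, a description of these libraries with no p. GC content and length came from the reference transcripts, and the trend was a polynomial of degree 3.

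The scripts were tested on simulated data. In counts simulated for replicate 2 against replicate 1, 100 genes changed 3-fold and 100 changed 8-fold among 17170 tested, 100% of each were called, and there were 0 false calls. These counts held sampling noise only, and the changed genes had a summed count of at least 100. The real libraries differed by more than sampling noise, so 0 false calls is no error rate for them. A simulated coefficient of variation of 0.15 was returned as 0.151 over 14151 genes. Alternatives included DESeq2 1.42.0 size factors, total and spike-in scaling, other pseudocounts, filters and units, and leaving out each replicate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The depth was 41760197 and 49256468 expected counts, and over the 38884247 and 45975100 of them on genes 3 counts correspond to 0.0772 and 0.0653 CPM.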

Results

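Total RNA was sequenced from the midbrain of B6NCrl mouse embryos at embryonic day 11.5, when the neural tube is patterned and neurons are being formed. The labels give 1 group with 2 biological replicates and no treatment or other condition. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos, both of mixed sex. Each library started from 10 ng of RNA longer than 200 nt with added ERCC spike-ins, which are synthetic RNAs of known amount. The gene tables held 41760197 expected counts in replicate 1 and 49256468 in replicate 2, of which 38884247 and 45975100 fell on genes. With 1 group, genes and gene lists were compared with each other within each library, and the libraries were then compared with each other. Values are mean TPM (relative transcript abundance, as deposited) ± SD over the 2 libraries (n = 2) unless stated.

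Of 43346 genes in the tables, 13895 reached 1 TPM in both libraries, 12496 of them protein-coding. The others included 222 long intergenic noncoding RNA genes, 235 antisense genes and 472 pseudogenes. The 10 most abundant nuclear genes were led by Gm42418 (8779.7 ± 436 TPM) and by Hbb-y, an embryonic beta-type globin (8311 ± 22.0 TPM). They also included the alpha-tubulin gene Tuba1a (6672 ± 180 TPM), Actb (4693 ± 144 TPM), Tmsb4x (4575 ± 159 TPM), the globin Hba-a2 (4408 ± 21.7 TPM) and Ppia (4159.7 ± 39.7 TPM). The remaining 3 were Gm28437 (5098 ± 251 TPM), Hist1h2ap (4659 ± 223 TPM) and Rn7s2 (4149.85 ± 640 TPM). Gm42418 overlaps a ribosomal RNA repeat, Gm28437 resembles mitochondrial sequence, and Hist1h2ap, Hba-a2 and Rn7s2 have near-identical copies, so their values are uncertain. For Rn7s2 the deposited interval, which lies around the posterior mean TPM and need not hold the TPM given here, ran from 821 to 5482 TPM in replicate 1, against 4475 to 4513 TPM for Actb.

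Genes of the midbrain and its border with the hindbrain were present, forebrain genes were lower, and Hox genes were close to absent. Otx2, a homeobox gene of the forebrain and midbrain (mm10 chromosome 14, 48657677 to 48673819), had 170.35 ± 1.30 TPM. It led the dorsal midbrain list, in which all 11 members reached 1 TPM in both libraries, followed by the ephrins Efna2 (65.0 ± 7.72 TPM) and Efna5 (58.6 ± 3.92 TPM). The isthmic organizer is the signalling centre at the midbrain-hindbrain border, and 12 of its 13 listed genes reached 1 TPM, with Cnpy1 (99.8 ± 1.34 TPM), Fgf17 (13.6 ± 3.58 TPM) and Wnt1 (9.83 ± 1.38 TPM) highest. Fgf8, its best-known secreted signal, had 7.735 ± 1.65 TPM, En1 had 5.615 ± 0.955 TPM, and Pax2 had 0.43 and 0.26 TPM in the 2 libraries.

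Ventral genes were also present, since all 16 floor plate and ventral progenitor genes reached 1 TPM, with Msx1 (74.3 ± 8.31 TPM), Spon1 (47.9 ± 0.127 TPM) and Wnt5a (22.7 ± 1.75 TPM) highest. Msx1 is also a listed BMP target and Lmx1b a listed isthmic gene, so their levels may not come from ventral tissue alone. Shh, the floor plate signal, had 4.71 ± 1.15 TPM. Of 18 forebrain genes, 10 reached 1 TPM, led by Lhx2 (44.9 ± 3.51 TPM), Dlx1 (11.8 ± 1.91 TPM) and Emx2 (9.35 ± 0.02 TPM). Of 29 Hox and other hindbrain genes, 1 reached 1 TPM, and Hoxa2 had 0.165 ± 0.0636 TPM. Hoxb9, Hoxc8 and Hoxd10 had 0 counts in both libraries, a result that allows up to 0.0772 CPM (counts scaled to library size) in replicate 1 and 0.0653 in replicate 2.

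The 24 isthmic and dorsal midbrain genes had a median of 7.57 TPM, against 2.25 TPM for the forebrain list and 0.015 TPM for the Hox list. On the log2(TPM + 1) scale the midbrain median exceeded the forebrain median by 1.47 ± 0.13 (n = 2, higher in 2 of 2 libraries, permutation p across genes = 0.0134 and 0.0053, adjusted p = 0.0267 and 0.0142). The excess over the Hox median was 3.12 ± 0.12 (n = 2, higher in 2 of 2 libraries, permutation p = 1e-05 in each, the smallest 100000 permutations can give, adjusted p = 4e-05). These tests permuted genes between lists within a library, two-sided, and genes are not independent replicates. The forebrain difference depended on genes near the detection limit, since it was 0.65 with permutation p = 0.381 over members at 1 TPM or more, and the size of the Hox difference depended on the pseudocount, since it was 6.28 (permutation p = 1e-05) with log2(TPM + 0.1).

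Of 29 gene pairs, 27 differed by more than their deposited intervals in both libraries. Otx2 was 22.7-fold above Gbx2, which marks the hindbrain side of the border (7.405 ± 0.0354 TPM). En1 was 2.71-fold above En2 (2.005 ± 0.290 TPM) and 21.7-fold above Hoxa2 (5.65-fold on TPM + 1). Pax3 (30.5 ± 1.65 TPM) was 11.9-fold above Pax7 (2.48 ± 0.141 TPM), and Fgf17 was 1.74-fold above Fgf8. In the ventral list, Lmx1a (13.5 ± 1.30 TPM) was 7.95-fold above Lmx1b, and Foxa2 (12.6 ± 1.55 TPM) was 1.93-fold above Foxa1. Folds were computed on TPM + 0.1, and those over genes under 1 TPM depend on that addition.

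**Figure D1:**
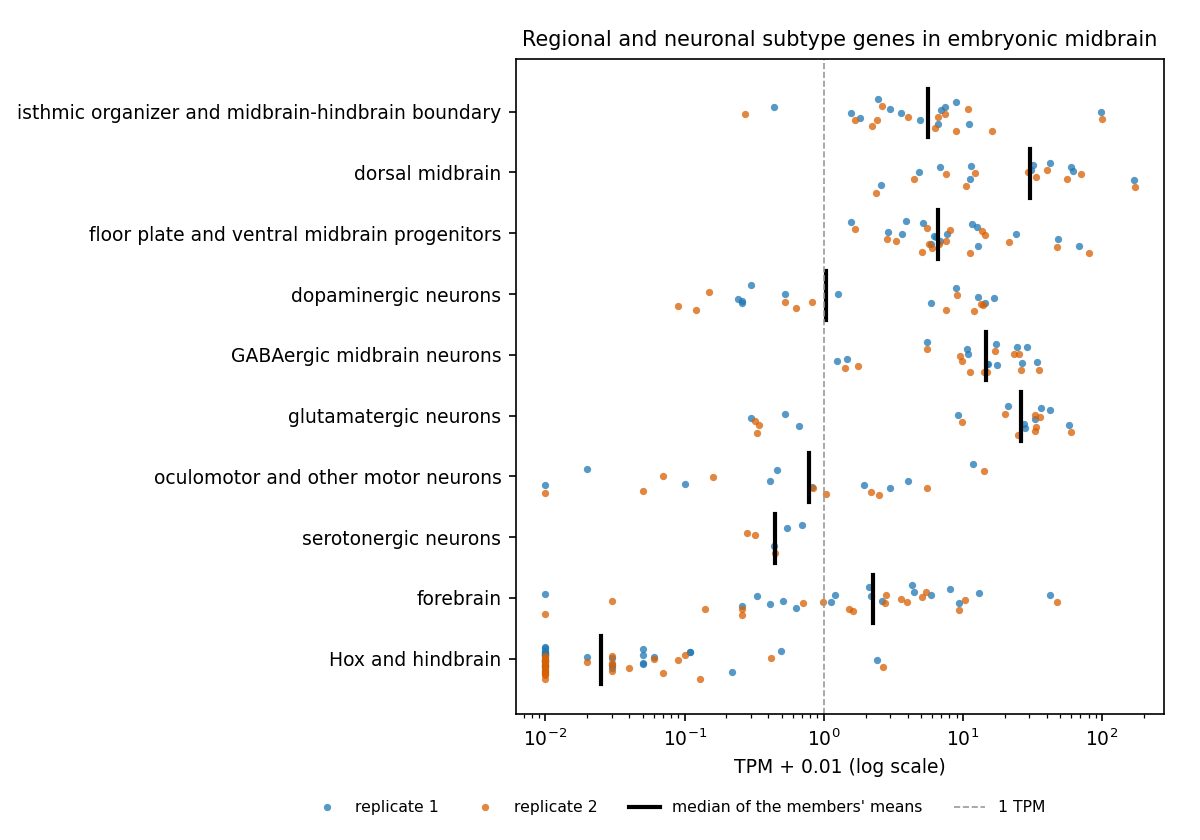
TPM + 0.01 on a log axis for each gene of 10 regional and neuronal lists, with 1 point per gene and library and a bar at the median of the genes' means. Dorsal midbrain genes have a median of 30.5 TPM and Hox and hindbrain genes a median of 0.015 TPM.

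Most listed excitatory and all listed inhibitory neuron genes reached 1 TPM, while fewer of the dopaminergic, motor and serotonergic genes did. All 13 GABAergic genes reached 1 TPM, led by the transcription factors Tal2 (34.8 ± 0.78 TPM), Lhx1 (27.0 ± 2.45 TPM) and Gata3 (26.4 ± 0.233 TPM). Erythroid genes were abundant too, and whether blood cells contributed to listed genes such as Tal1, Gata2 and Zfpm1 was not tested. Of 11 glutamatergic genes, 8 did so, led by Neurog2 (58.9 ± 1.22 TPM), Pou4f1 (39.1 ± 4.67 TPM) and Lhx9 (34.7 ± 2.53 TPM). The vesicular glutamate transporter Slc17a6 (26.3 ± 2.26 TPM) was 64.4-fold above its relative Slc17a7 (20.8-fold on TPM + 1) and 15.5-fold above the GABA transporter Slc32a1 (1.605 ± 0.191 TPM). Gata3 was 1.76-fold above Gata2 (14.9 ± 0.0778 TPM), and the GABA-synthesizing enzymes Gad1 (10.3 ± 0.70 TPM) and Gad2 (14.5 ± 4.53 TPM) were not separated by their intervals in both libraries. The glutamatergic median was above the GABAergic one by 0.80 ± 0.04 (log2, n = 2, permutation p = 0.224 and 0.396, adjusted p = 0.358 and 0.528), which did not pass the threshold. It was 0.01 (permutation p = 0.990) with means in place of medians and 1.06 (permutation p = 0.0628) over members at 1 TPM or more.

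Dopaminergic genes divided into those already present and those near the detection limit. Ddc (15.4 ± 2.03 TPM), Slc18a2 (13.2 ± 1.61 TPM), Nr4a2 (13.1 ± 0.368 TPM), Th (8.97 ± 0.0707 TPM) and Sox6 (6.75 ± 1.17 TPM) were the 5 of 11 above 1 TPM in both libraries. Th encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, and Ddc, the next enzyme, was 1.70-fold above it. Pitx3 had 0.215 ± 0.106 TPM on 10 and 3 counts, 43.3-fold below Nr4a2 on TPM + 0.1 and 11.7-fold on TPM + 1, and the dopamine transporter gene Slc6a3 had 21 and 9 counts. Of 10 motor neuron genes, 4 reached 1 TPM, led by Isl1 (13.01 ± 1.79 TPM), Isl2 (4.73 ± 1.05 TPM) and Prph (2.75 ± 0.36 TPM). None of the 3 serotonergic genes did in either library (Tph2 0.48 ± 0.30, Slc6a4 0.43 ± 0.01 and Fev 0.42 ± 0.16 TPM).

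Proliferating progenitors and young neurons were both prominent. All 20 cell cycle genes exceeded 10 TPM, with a median of 192 TPM, and Rrm2 (419 ± 8.91 TPM), Ccnd2 (382 ± 15.7 TPM) and Top2a (331 ± 1.12 TPM) were highest. All 16 neural progenitor genes reached 1 TPM, with a median of 53.7 TPM, led by the intermediate filament gene Vim (1176 ± 1.39 TPM), Fabp7 (847 ± 4.93 TPM) and the NOTCH target Hes5 (379 ± 45.0 TPM). Of 16 neuron genes 15 did, with a median of 79.1 TPM, led by the neuronal tubulin Tubb3 (619 ± 38.1 TPM), Stmn2 (272 ± 7.45 TPM) and Gap43 (239 ± 10.1 TPM). The progenitor median differed from the neuron median by -0.55 ± 0.33 (log2, n = 2, permutation p = 0.639 and 0.851, adjusted p = 0.731 and 0.851), which did not pass the threshold, and its sign turned (0.40, permutation p = 0.684) with means in place of medians.

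Synaptic genes had a median of 3.45 TPM, with 14 of 16 at 1 TPM or more. Dlg4 (10.3 ± 3.18 TPM), Syn1 (10.2 ± 1.65 TPM) and Gria2 (9.75 ± 0.91 TPM) were highest. The chloride importer Slc12a2 (8.035 ± 0.446 TPM) was 6.14-fold above the exporter Slc12a5 (1.225 ± 0.0778 TPM), or 4.06-fold on TPM + 1. Grin2b (0.64 ± 0.0707 TPM) and Grin2a (0.235 ± 0.0495 TPM) were separated by their intervals in replicate 2 but not in replicate 1. Among progenitor pairs, Hes5 was 15.4-fold above Hes1, Sox9 (81.5 ± 0.743 TPM) was 2.44-fold above Sox2 (33.35 ± 0.198 TPM), and Ccnd2 was 1.85-fold above Ccnd1. Tubb3 was 10.7-fold above Nes, and the pluripotency gene Pou5f1 had 0 and 2 counts.

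Blood, vessel and mesenchymal genes were present beside the neural ones. All 12 measured erythroid genes reached 1 TPM, led by Hbb-y, Hba-a2 and Hba-x (2485 ± 36.8 TPM), and Hbb-y was 3.92-fold above Hbb-bh1 (2119.7 ± 36.4 TPM). The 10 endothelial genes had a median of 16.6 TPM, with Cldn5 (22.6 ± 1.12 TPM), Esam (20.95 ± 2.53 TPM) and Kdr (20.1 ± 1.82 TPM) highest. The 6 mural cell genes were led by Acta2 (27.9 ± 0.30 TPM), Notch3 (15.2 ± 0.80 TPM) and Pdgfrb (12.9 ± 0.94 TPM), and the 10 mesenchymal genes by Col3a1 (325 ± 16.2 TPM), Lum (126 ± 10.1 TPM) and Col1a2 (110.46 ± 1.09 TPM). Of 11 microglia and macrophage genes 10 reached 1 TPM, led by the complement genes C1qb (25.3 ± 1.86 TPM), C1qc (14.0 ± 0.71 TPM) and C1qa (11.3 ± 0.62 TPM).

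Mature glia and non-brain tissues left weaker traces. Of 7 astrocyte genes 3 reached 1 TPM, namely Gja1 (104.6 ± 8.34 TPM) and Slc1a2 (12.1 ± 0.08 TPM), which progenitors also express, and Aldh1l1 (3.07 ± 0.18 TPM), and the mature astrocyte gene Gfap had 1 and 7 counts. Of 10 oligodendrocyte lineage genes 6 did, led by Pdgfra (14.7 ± 1.84 TPM) and Cnp (12.5 ± 0.70 TPM), and Olig2 was 2.43-fold above Olig1. Sox10 (0.61 ± 0.17 TPM) and Cspg4 (0.61 ± 0.11 TPM) of the same list stayed under 1 TPM. Neural crest and sensory ganglion genes were led by Prdm12 (8.78 ± 0.16 TPM), while Sox10 and Foxd3 (0.06 ± 0.03 TPM) stayed low, with 4 of 6 at 1 TPM or more. Surface epithelium reached it for 5 of 8 genes, led by Krt8 (8.08 ± 0.55 TPM), Epcam (4.75 ± 0.69 TPM) and Cdh1 (4.64 ± 0.43 TPM). For skeletal muscle this held for 2 of 5 genes, Tnnt1 (5.62 ± 0.77 TPM) and Actc1 (1.39 ± 0.19 TPM), ahead of Myl1 (0.35 ± 0.10 TPM). Choroid plexus had 1 of 5, Folr1 (9.21 ± 0.45 TPM), ahead of Ttr (0.74 ± 0.26 TPM) and Clic6 (0.46 ± 0.13 TPM).

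**Figure D2:**
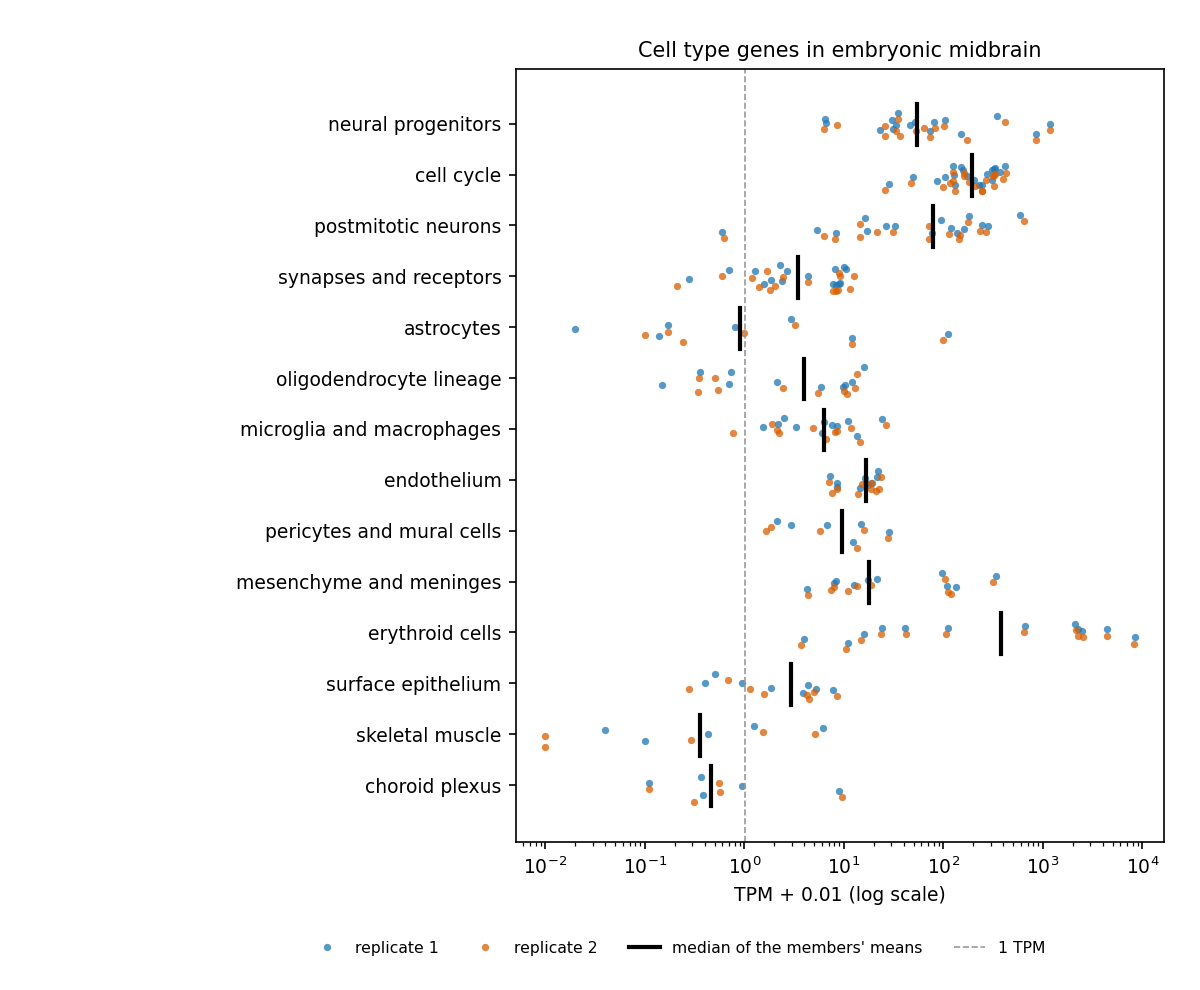
TPM + 0.01 on a log axis for each gene of 14 cell type lists, with 1 point per gene and library and a bar at the median of the genes' means. Cell cycle genes have a median of 192 TPM and neuron genes a median of 79.1 TPM, while choroid plexus and skeletal muscle genes lie mostly below 1 TPM.

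Most genes kept the same leading transcript in both libraries. For Pkm, a pyruvate kinase gene, Pkm-201 made up 91.3% ± 0.417 and Pkm-202 made up 8.735% ± 0.417. Cdc42-202 made up 88.1% ± 0.0283 of Cdc42, Ncam1-204 made up 80.1% ± 0.827 of Ncam1, and Rest-201 made up 92.7% ± 2.76 of Rest. Cltb was shared almost evenly between Cltb-202 (51.7% ± 0.615) and Cltb-201 (48.0% ± 0.375), and Otx2 was mainly Otx2-201 (56.3% ± 0.12) with Otx2-202 (29.4% ± 0.891). Low genes were less stable, as the leading Grin1 transcript took 49.2% of Grin1 in replicate 1 and 29.6% in replicate 2. Of 9584 genes with at least 2 transcripts and 1 TPM in both libraries, 8769 (91.5%, exact 95% interval 90.9% to 92.0%) had the same leading transcript. That interval covers counting of genes only.

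Globin genes took 0.747% of gene counts in replicate 1 and 0.758% in replicate 2, and the mitochondrial genome took 1.25% and 1.16%. The mitochondrial share leaves out Gm28437, which resembles mitochondrial sequence and held 96599 and 107779 counts, so it may be too low. Cytosolic ribosomal protein genes, of which 79 of 82 reached 1 TPM, took 2.00% and 2.12%, led by Rpl41 (2172 ± 187 TPM), Rps19 (1432 ± 106 TPM) and Rpl32 (1403 ± 25.4 TPM). On the mitochondrial genome 15 of 37 genes reached 1 TPM, led by mt-Atp6 (5848 ± 919 TPM), mt-Atp8 (5224 ± 579 TPM) and mt-Cytb (2385 ± 241 TPM). Replication-dependent histones took 0.162% and 0.176%, led by Hist1h2ap, Hist1h4d (298 ± 50.5 TPM) and Hist1h3i (221 ± 9.62 TPM), a family of near-identical copies. The 10 genes with the most counts took 4.93% and 4.84%, and spike-ins took 6.89% and 6.66% of all counts. Wilson 95% intervals of these shares cover counting error only and are narrower than the gap between the libraries.

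The libraries were close to each other, with Pearson's r = 0.995 and Spearman's rho = 0.994 across the 13895 genes on log2(TPM + 1). Vim (1177 and 1175 TPM), Sox2 and Th differed little, and 83.0% of genes differed by less than 1.2-fold. The median absolute log2 difference was 0.11, and the common biological coefficient of variation over 14052 genes was 7.80%. The libraries differed by more than sampling noise (chi-square per degree of freedom 10.3) and were counted as 2 samples. Spike-ins, which carry no biology, had a median absolute log2 difference of 0.10 over 60 sequences, against 0.11 for genes of matched count.

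Between the pools, 481 of 17148 tested genes (2.81%) differed at least 2-fold beyond sampling noise, 224 higher and 257 lower in replicate 2 (two-sided exact binomial test, Benjamini-Hochberg). This test compares 2 libraries and not 2 conditions. With spike-in scaling 258 were higher and 215 lower, 155 genes passed with an assumed coefficient of variation of 0.1 (edgeR exact test), and 5990 passed without the 2-fold minimum. Among the 10 largest increases, Tbr1, a transcription factor of glutamatergic neurons (chromosome 2, 61802930 to 61814114), had 39 counts in replicate 1 and 189 in replicate 2 (log2 ratio 2.00, exact binomial adjusted p = 1.06e-17). The tachykinin receptor gene Tacr3 had 21 and 80 counts (log2 ratio 1.64). The muscarinic receptor gene Chrm2 (83 and 29 counts, log2 ratio -1.73), Cyp2u1 (76 and 27 counts, -1.70) and Dcdc5 (77 and 28 counts, -1.67) were lower in replicate 2. For Dcdc5 the deposited intervals overlapped (0.911 to 1.76 TPM in replicate 1, 0.332 to 1.13 TPM in replicate 2), and for Tbr1, Tacr3, Chrm2 and Cyp2u1 they did not.

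The remaining 15 genes of that rule had fractional counts, in which reads are split between similar sequences, and are uncertain. Those higher in replicate 2 were Gm14288, Duxbl2, Gm12191, Zfhx2os, Pcdha11, Gm20425, Gm10243 and Gm15429, with log2 ratios from 7.5 for Gm14288 to 1.67 for Gm15429. Those lower were Gm8783, Rpl30-ps9, Gm20388, Tom1, mt-Nd4l, Hist2h3c1 and BC037034, with log2 ratios from -7.38 for Gm8783 to -1.80 for BC037034. Of the 481 genes, 204 had a fractional count, 257 had deposited intervals that overlapped between the libraries, and 82 had a mean count of at least 50.

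Members of 7 lists were among the 481. In the forebrain list 3 of 15 tested members passed over all genes and also 3 when adjusted over the list alone. Of these, 2 were higher in replicate 2, Tbr1 among them, and 1 was lower. The lower one was Rax (log2 ratio -2.01, exact binomial adjusted p = 5.39e-06), with a fractional count in replicate 2. The dopaminergic list had 2 of 9, Aldh1a1 higher and Slc6a3 lower, and the motor neuron list had 2 of 7, Phox2a higher and Slc18a3 lower. Histones had 6 of 58, 4 higher and 2 lower, and the retinoic acid list had 2 of 11, Aldh1a1 higher and Aldh1a3 lower. Among serotonergic genes Tph2 was lower (1 of 3), and on the mitochondrial genome mt-Nd4l was lower (1 of 15). No member of the other lists passed with the 2-fold minimum. Without it, the exact binomial test passed 5990 of all 17148 tested genes. By list it passed 5 of 13 isthmic genes, 5 of 11 dorsal midbrain genes, 7 of 16 progenitor genes and 10 of 16 neuron genes, 8 of 20 cell cycle genes, 3 of 10 endothelial genes and 3 of 12 erythroid genes. These list counts were not tested against the count over all genes.

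As lists, 7 of 41 had a median log2 ratio outside the middle 95% of 10000 random lists matched on expression, where lists of unrelated genes give about 2.05. Members of a list can vary together and some lists share members, which the random lists do not copy. The count of 7 is therefore no measure of an excess. Isthmic genes had a median of 0.27 (percentile 99.9), with Fgf17 at 0.55, Fgf8 at 0.47 and En1 at 0.36 against Pax2 at -0.67, Pax5 at -0.36 and Sp8 at -0.07, and WNT targets had 0.24 (percentile 99.6), with Nkd1 at 0.26, Axin2 at 0.20 and Lef1 at 0.00. Structural RNAs without a poly(A) tail (0.34, on 3 tested members), histones (0.13) and ribosomal protein genes (0.09) were also higher in replicate 2. For the structural RNAs a difference in capture between the libraries was not tested. Forebrain genes had a median of -0.28 (percentile 0.11), with Dlx1 at -0.28, Six3 at -0.62 and Dlx5 at -0.55 against Lhx2 at 0.13 and Emx2 at 0.10, and the mitochondrial genome had -0.10. The log2 ratio also followed GC content across 13985 genes (Spearman's rho 0.43), with medians of -0.09 and 0.14 when the lowest and the highest of 5 equal groups by GC content were compared. After removal of the trend over GC content and length, chosen after seeing the data, 3 of the 7 stayed outside, the forebrain list (-0.36), WNT targets (0.18) and ribosomal protein genes (0.03). GABAergic (-0.14), cell cycle (0.05), neuron (-0.06), erythroid (-0.08) and imprinted (-0.06) genes then also lay outside.

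**Figure D3:**
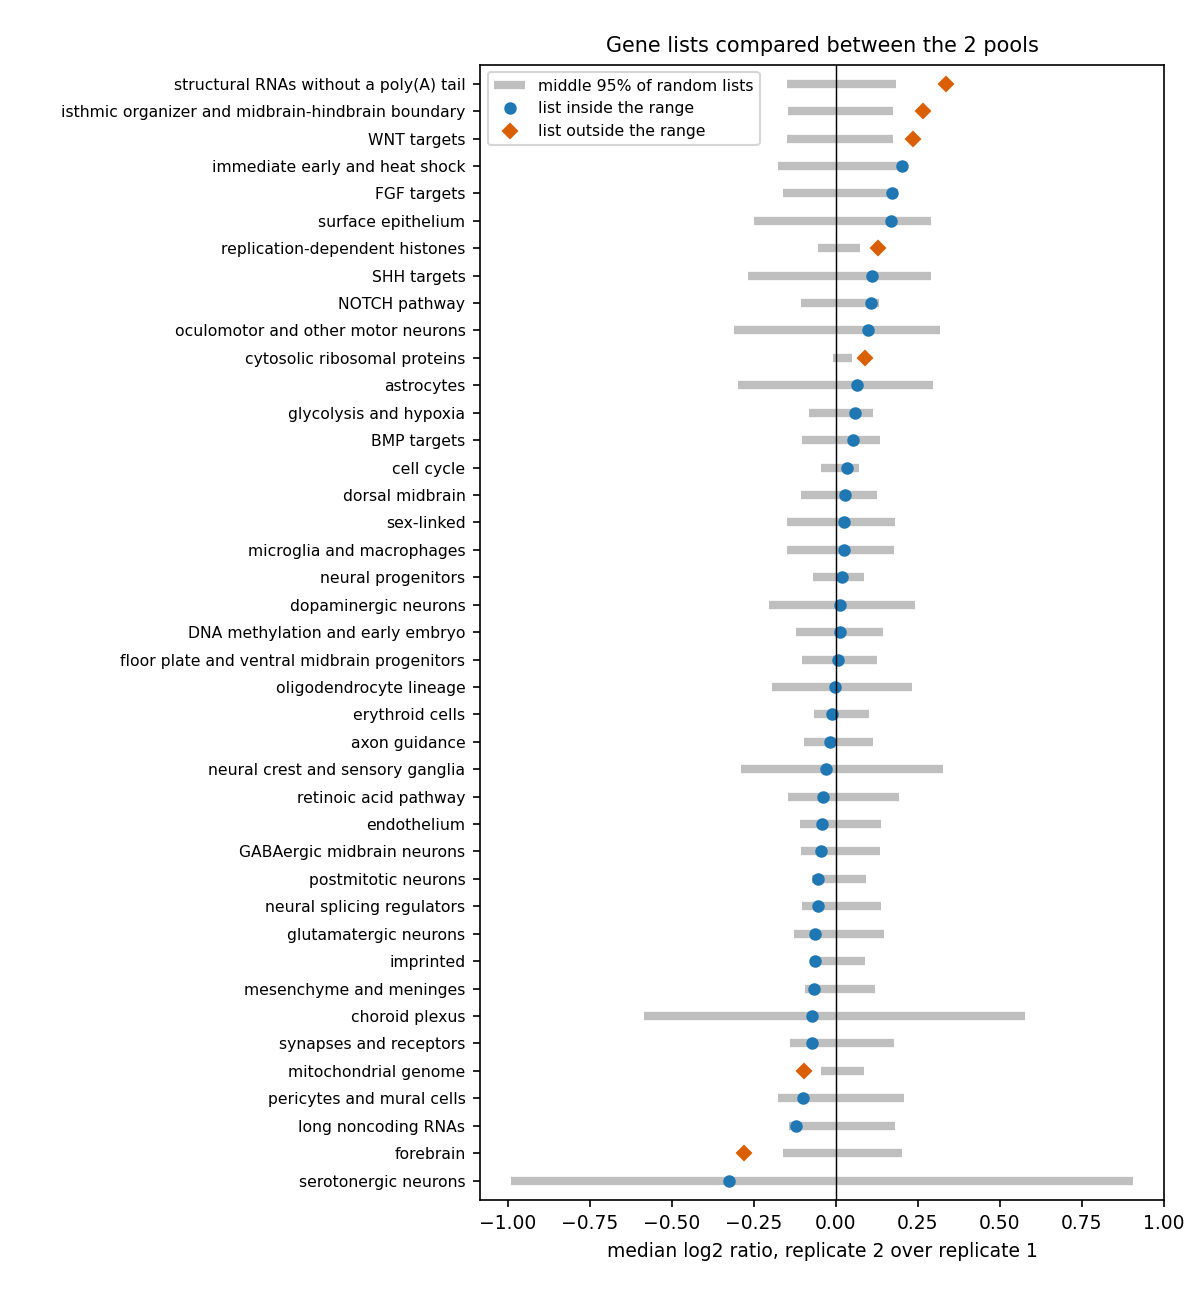
Median log2 ratio of replicate 2 over replicate 1 for each of 41 gene lists (points), with the middle 95% of 10000 random lists of the same size and expression (grey bars). The 7 lists outside their bars are drawn as diamonds, from structural RNAs at 0.34 to forebrain genes at -0.28.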

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

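Rows with bare numeric identifiers belong to no comparison and have no control library, yet their summed expected count lay above the 3 counts that a count of 0 allows in both libraries. The sum was 4.44 in replicate 1 and 13.25 in replicate 2. No explanation was tested.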

How the results depend on the processing

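The GC and length correction and the TPM rescaled without spike-ins were chosen after seeing the data. No paired analysis was possible because the labels give 1 group. For the 4 list contrasts 25 alternative values kept their direction and their side of the threshold, 1 lost its call and 1 turned its direction, and of the other main results 20 alternative values, nearly all of them counts within 1.5 times the reported ones, were kept and 16 moved beyond the limit set for each. The midbrain difference from forebrain genes fell to 0.65 (permutation p = 0.381) when members under 1 TPM were left out, which removes the lowest forebrain genes, and no Hox contrast was computed that way because 1 Hox and hindbrain gene is left. The progenitor difference from neurons, which never passed, turned to 0.40 with means of log2 values, and the glutamatergic difference from GABAergic genes, which never passed either, fell to 0.01 (permutation p = 0.990), and the cause was not tested. The Hox difference was 6.28 with log2(TPM + 0.1), because the Hox median lies near 0.

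Detected genes numbered 8428 at 10 TPM, because the threshold is higher, and 14204 without spike-ins in the TPM. Pearson's r was 0.9939 with log2(TPM + 0.1), 0.9938 without a filter, 0.995 at 10 TPM and 0.9954 with FPKM, and the median absolute log2 difference was 0.1179, 0.1108, 0.0905 and 0.1002 in the same order. The coefficient of variation was 0.09 without a filter. Genes beyond sampling noise numbered 82 at a summed count of 100, 5990 with no minimum fold and 155 with an assumed coefficient of variation of 0.1 (edgeR exact test), against 481. The same leading transcript was found for 94.7% of genes at 10 TPM, 86.2% without a filter and 90.5% with posterior means. Lists outside the random range numbered 8 after the GC and length correction, against 7. Spike-in scaling called 473 genes, 54.5% of them higher in replicate 2, against 46.6%. No pair changed direction with TPM + 1 or FPKM, but 8 of 29 pair folds shrank by over 1.5 times with TPM + 1, since a larger addition lowers ratios over genes near 0. With 2 libraries and 1 group, depth limits the genes with few counts, and the number of libraries limits every statement about midbrain in general.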

Other observations

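Tests on the forebrain list's correction and counting noise, on telencephalic and cerebellar genes, and on near-identical copies were chosen only after the result was seen, and the added marker lists were written after the libraries had been compared.

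Signalling genes of several pathways were expressed. WNT targets had a median of 7.63 TPM with Lef1 (52.9 ± 0.16 TPM, SD, n = 2 throughout), Nkd1 (22.7 ± 2.76 TPM) and Axin2 (16.75 ± 1.34 TPM) highest. FGF targets were led by Dusp6 (29.1 ± 3.10 TPM), Spry2 (21.1 ± 0.69 TPM) and Etv5 (9.02 ± 1.85 TPM), SHH targets by Ptch1 (15.25 ± 0.35 TPM) and Hhip (4.12 ± 0.69 TPM), and BMP targets by Id3 (399.9 ± 25.9 TPM), Id2 (274 ± 13.3 TPM) and Msx1. NOTCH pathway genes were led by Hes5, Dll3 (68.6 ± 0.58 TPM) and Dll1 (49.4 ± 4.35 TPM). In the retinoic acid list the binding proteins Crabp1 (881 ± 21.5 TPM) and Crabp2 (413 ± 3.16 TPM) were high, while the synthesis genes Aldh1a1, Aldh1a2 and Aldh1a3 stayed under 1 TPM. Guidance genes all reached 1 TPM, 16 of 16, led by Epha7 (60.4 ± 5.64 TPM), Slit2 (35.9 ± 2.47 TPM) and Robo3 (32.5 ± 1.86 TPM).

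Among regulators, the splicing factor Ptbp2 (227 ± 11.0 TPM) was 1.89-fold above Ptbp1 (120.6 ± 14.6 TPM), and Elavl2 followed (75.3 ± 4.82 TPM). Ezh2 (109.8 ± 0.495 TPM), Dnmt1 (44.5 TPM in both libraries) and Dnmt3a (39.6 ± 3.98 TPM) led the list of DNA methylation and early embryo genes. In that list Dnmt3a was 3.99-fold above Dnmt3b and Lin28b was 3.93-fold above Lin28a. All 16 imprinted genes reached 1 TPM, led by Mest (986 ± 17.9 TPM), Cdkn1c (453 ± 5.30 TPM) and Ndn (325 ± 6.63 TPM). Noncoding RNAs were led by Malat1 (2216 ± 124 TPM), Pantr1 (437 ± 15.8 TPM) and Miat (28.7 ± 4.14 TPM), and RNAs without a poly(A) tail by Rn7sk (155 ± 31.7 TPM), Rpph1 (45.5 ± 7.25 TPM) and Rmrp (20.7 ± 0.64 TPM). Whether RNAs without a poly(A) tail entered the libraries as fully as other RNAs was not tested, so their levels may understate their amounts. Glycolysis genes were led by Ldha (1168 ± 23.3 TPM), Eno1 (1139.9 ± 48.8 TPM) and Aldoa (384 ± 11.6 TPM), and stress genes by Dnajb1 (67.3 ± 7.06 TPM), Ier2 (39.4 ± 1.89 TPM) and Jun (21.1 ± 1.73 TPM). Both pools held Xist (16.9 ± 3.57 TPM) and the Y-linked genes Eif2s3y (22.5 ± 1.54 TPM) and Kdm5d (12.1 ± 2.92 TPM). Sex-linked genes moved both ways in replicate 2 against replicate 1, Xist (log2 ratio -0.44) and Tsix (-0.35) down, Kdm5d (0.44) and Ddx3y (0.33) up. Eif2s3y (0.07) and Uty (-0.02) moved little, and whether the pools differed in their mix of sexes was not tested.

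The isthmic list was higher and the forebrain list lower in replicate 2. In a test of counting noise 0 of 10000 simulated lists without a difference reached either median, which decides nothing because the libraries exceeded counting error as a whole (chi-square per degree of freedom 10.3) and the lists were picked for their extreme medians. GC content and length are a candidate explanation for the isthmic part, because removing that trend took its median from 0.27 (random lists -0.15 to 0.18) to 0.13 (random lists -0.15 to 0.14), percentile 96.4, and the genes' median GC content is 56.0% against 49.97% for all genes. The same correction left the forebrain median at percentile 0.01, although 7 of its 15 tested members were higher in replicate 2 and resampling within counting noise gave -0.35 to 0.11 for its median. Whether the pools held more tissue from behind the isthmus (cerebellar and rhombic lip list, percentile 65.4) or less ventral forebrain and hypothalamus (percentile 16.8, with Gsx1, Foxd1 and Pomc the highest) cannot be told apart at these counts, and beyond tissue content no biological explanation was tested because both pools belong to 1 group.

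Tbr1 and Eomes were higher in replicate 2, with 39 and 189 counts for Tbr1 and 23 and 84 for Eomes, which was chosen after its values were seen. The mean log2 ratio of Tbr1 and Eomes was 1.79 before and 1.72 after the correction for GC content and length. The trend across all genes thus accounts for little of it. This test could hardly have come out otherwise, because the lowest and highest GC groups differed by only 0.22, so it is no further evidence. Telencephalic or cerebellar tissue stays open, because the listed genes with a mean under 1 TPM, 5 of 8 telencephalic and 4 of 7 cerebellar, had pooled log2 ratios of 0.32 (exact interval -0.000236 to 0.64) and 0.23 (-0.17 to 0.64). An earlier test on the whole lists (medians 0.04 and 0.06, percentiles 60.2 and 65.4), which neither tissue passed, was dropped because abundant members such as Nr2e1 (24.8 TPM) and Irx2 (30.1 TPM) would hide a small share. A later one, against a set part of the Eomes log2 ratio (0.79), was dropped because that part was assumed, and both pooled upper bounds lay below it while 2 of 5 telencephalic members, such as Neurod6 (1 and 16 counts, against 32 and 18 for Trp73), and 0 of 4 cerebellar members lay above it.

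Among genes that differed at least 2-fold, reads shared between near-identical copies may account for part. A fractional count was found in 42.4% of the 481 genes (exact interval 37.9% to 47.0%) and in 12.3% (9.47% to 15.5%) of other genes of matched count. The other 277 genes had whole counts in both libraries (within 0.005), and 121 of them were higher and 156 lower in replicate 2. A whole count shows no split of reads in the estimate, but it defined this group, so it is no separate test of sharing. What those genes have in common was not tested.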
